A study of Mus musculus with 4 samples.

How the data were processed

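The data were droplet single-cell RNA sequencing of kidney cells from male C57BL/6 mice given intraperitoneal glyoxylate for 0, 1, 4 or 7 days, with 1 library per time point. Per the labels the chemistry was 10x 3' and the kidneys were digested with trypsin and DNase. The values are UMI counts per gene and cell as deposited by the authors, with no normalization. Cell Ranger 3.1.0 and the mm10 build were used per the submitters' processing notes, while the matrix header names software version 3.0.1. The annotation release and the cell calling settings are not given in the sources used here. Gene positions were taken from GENCODE M21 by gene ID. Each matrix held 27998 genes, and the deposited cell lists held 16426, 12730, 16427 and 15087 barcodes for D0, D1, D4 and D7. Their lowest cell depths were 500, 500, 2919 and 2773 UMIs, so cell calling differed between the first and the last pair of libraries.

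Cells with at least 300 genes, at least 500 UMIs and at most 50% mitochondrial UMIs passed, and the mitochondrial limit removed 11.8, 10.2, 1.97 and 4.19% of barcodes. Doublets were scored with Scrublet in each library. Its automatic threshold called 3 and 1 cells at D0 and D1 but 17.1 and 15.1% at D4 and D7. For that reason the highest scores were removed at an expected rate of 0.8% per 1000 cells, which took out 11.6, 9.10, 12.9 and 11.6%, and this was chosen after the scores were seen. Counts were scaled to 10000 per cell and log-transformed, and all libraries were clustered together without integration, from 2000 variable genes, 30 components, 20 neighbours and Leiden resolution 1. Genes of the result lists and mitochondrial, ribosomal protein and haemoglobin genes were left out of the variable genes. The 24 clusters were named from fixed markers of 16 classes, and classes are called "-like" because no other evidence of identity was used. Of these clusters, 22 were named.

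UMIs of a class were summed within a library and each gene's count was scaled to that sum (CPM). Ratios of single genes have exact intervals for a ratio of 2 Poisson counts, shares have exact Clopper-Pearson intervals, a share of 0 has the limit that 3 counts of the total give, and list medians have intervals from 1000 Poisson resamples. All are 95% intervals. With 1 library per time point no test between animals was possible, and no p-value was computed from cells. List medians are medians of log2 ratios of CPM plus 1 over members with at least 50 UMIs in the 2 libraries, and were set beside 10000 random lists of the same size matched over 25 expression bins. A list member is called higher or lower from a 1.5-fold ratio of CPM plus 1, while the folds printed for single genes are ratios of CPM. A fold against 0 UMIs is a lower bound from a floor of 3 counts in that library. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs.

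The 24 gene lists, the cell type markers, the comparisons and the rule for naming genes were fixed before the data were examined. In proximal tubule-like cells the rule names the 8 genes with the highest and the 8 with the lowest ratio at each day, among genes with at least 100 UMIs in the pair and 50 CPM in the higher library. In other classes with at least 100 cells at D0 and D7 it names the 3 highest and 3 lowest at D7 whose level is at least 0.25 of that in the highest class. Mitochondrial, ribosomal protein, haemoglobin and unnamed model genes and the cell type markers were left out of it. For each list it names up to 4 members with the largest ratio at D7, and Havcr1, Lcn2 and Spp1 are always given. Examples in the text come from these members unless it says that they were chosen after their values were seen.

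RNA carried between classes was measured from the fixed markers of the source class, as the median over markers of the level in the receiving class divided by that in the source class. It can stem from free RNA or from doublets, which were not told apart. Where a class holds such RNA, the dilution of its own genes is the ratio of the remaining shares at both days. Alternatives fixed in advance were at most 25% mitochondrial UMIs, at least 1000 UMIs, doublets kept, Leiden resolution 2, edgeR TMM factors used as a scaling only, a minimum of 1 UMI, thinned cells and a pseudocount of 10 CPM. Added after the data were seen were a common floor of 3000 UMIs, the automatic Scrublet threshold, leaving out the cluster led by Havcr1 or also the one led by cell cycle genes, shares without thinning, and a limit of 25% mitochondrial UMIs within the named distal tubule-like and thick ascending limb-like cells. The ratios were tested on simulated data with 200 of 10306 genes changed. Both simulated libraries were Poisson draws from the D0 sums of proximal tubule-like cells. Recovered ratios were scored after the median ratio of the unchanged genes was subtracted, a step not applied to the reported ratios. Within 0.5 of the true log2 value were 52 of 53 genes lowered by 1 and 50 of 50 raised by 1, but 32 of 46 lowered by 2, with a median of -1.83 recovered for the last. Intervals covered the true value for 95.29% of genes, and 6 of 100 unchanged lists fell outside the random range. Such coverage follows from the Poisson draws, which the intervals assume, so it checks the computation only. It says nothing about differences between animals or libraries. Reads were not analysed here, so reads outside annotated genes and empty droplets could not be examined.

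Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.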

Results

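Kidneys of male C57BL/6 mice were taken before and after 1, 4 and 7 days of intraperitoneal glyoxylate, which the body turns into oxalate and which leads to calcium oxalate crystals in the tubules (D0, D1, D4 and D7 below). In proximal tubule-like cells, Havcr1 (Kim-1, a receptor that injured tubule cells make) was 264-fold higher at D7 than at D0, with a 95% interval from 128 to 659 and 1905 UMIs against 7. Spp1 (osteopontin, a secreted protein that binds calcium oxalate) was 8.83-fold higher (8.69 to 8.97), and the transporter gene Slco1a1 was lower at 0.395 times its D0 level (0.382 to 0.408). Mononuclear phagocyte-like cells made up 3.28% of cells with at least 3000 UMIs at D7 and 0.985% at D0, at a floor added after the data were seen. Their shares were 3.49 and 1.63% of all kept cells, but 1.26 and 0.931% at a finer clustering (resolution 2). Each time point has 1 library, so there are no replicates, and all intervals below are 95% intervals for counting error only.

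The assay was droplet single-cell RNA sequencing of digested kidney, with unique molecular identifier (UMI) counts as deposited by the authors. The 4 libraries held 99337001, 85009491, 91122085 and 94512170 UMIs at D0, D1, D4 and D7. Of their cells 12784, 10346, 14028 and 12783 were kept. Proximal tubule-like cells numbered 10725, 7709, 13002 and 11470, with median depths of 5324, 6312, 4750 and 5343.5 UMIs. Their UMIs were summed within a library, to 68396006, 59654796, 69461305 and 70394102, and each gene's UMIs were scaled to that sum (CPM). Folds are ratios of these CPM. Different clusters held much of the class in the 2 pairs of libraries. Those led by Cndp2 and Oat held 1673 and 1659 cells at D0 but 676 and 839 at D4, and the one led by Txnip 1167 at D0 but 3151 at D4. The deposited cell lists began at 500 UMIs at D0 and D1 but at 2919 at D4 and 2773 at D7, so shares that cross these pairs are also given for cells with at least 3000 UMIs. In the GENCODE M21 annotation of the mm10 build, which is not known to be the one used for the counts, Havcr1 (ENSMUSG00000040405) lies on chromosome 11 at 46735080 to 46779578 on the plus strand. Lcn2 (ENSMUSG00000026822) lies on chromosome 2 at 32384633 to 32388252 on the minus strand, and Spp1 (ENSMUSG00000029304) on chromosome 5 at 104435118 to 104441050 on the plus strand.

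Proximal tubule-like cells made up 83.9% of kept cells at D0 (83.2 to 84.5, exact binomial), 74.5% at D1 (73.7 to 75.3), 92.7% at D4 (92.2 to 93.1) and 89.7% at D7 (89.2 to 90.2). With at least 3000 UMIs per cell the shares were 93.3, 84.8, 92.7 and 90.1%. At this floor the D7 share was 0.966 times that of D0 (0.939 to 0.995), where it was 1.07 times over all kept cells. Mononuclear phagocyte-like cells, the macrophages and monocytes that clear debris and crystals, made up 1.63% at D0 (208 cells), 4.32% at D1 (447), 1.71% at D4 (240) and 3.49% at D7 (446). At the 3000 UMI floor they were 0.985, 4.34, 1.68 and 3.28%. That is 4.41 times the D0 share at D1 (3.45 to 5.69), 1.70 times at D4 (1.32 to 2.21) and 3.33 times at D7 (2.63 to 4.27). At clustering resolution 2 the D7 share of these cells was 1.26%, and with at most 25% mitochondrial UMIs it was 1.40%. This is because the Lyz2-led cluster then had no class name. Dendritic cell was its best class (scores of 0.429 and 0.463), and a cluster stays unnamed where another class has more markers among its top 10 genes. Lyz2, its leading gene at resolution 1, is itself a fixed phagocyte marker. T or NK cell-like cells were 2.07, 4.91, 1.53 and 1.18% of kept cells, and at the floor 5.18 times their D0 share at D1 (3.91 to 6.95) and 1.57 times at D7 (1.15 to 2.15). B cell-like cells, at 1.28, 1.99, 0.499 and 0.438% of kept cells, were 0.341 times their D0 share at D7, but 2.83 times at the floor (1.52 to 5.67; 52 cells against 13). Thick ascending limb-like cells at the floor were 2.07 times their D0 share at D1 (1.47 to 2.93) and 2.00 times at D7 (1.47 to 2.76). Distal convoluted and connecting tubule-like cells were 0.517 times at D4 (0.421 to 0.633) and 0.774 times at D7 (0.641 to 0.937). With at most 25% mitochondrial UMIs these 2 classes fell into 1 cluster, named thick ascending limb, which held 1.28% of cells at D0 (129 cells) and 3.14% at D7 (312 cells). Together the classes were 3.17% of kept cells at D0 and 3.29% at D7, and 3.72 and 3.399% with the automatic Scrublet threshold, where they also fell into 1 cluster. Of the distal convoluted and connecting tubule-like cells, 85 of 314 at D0 and 159 of 249 at D7 had at most 25% mitochondrial UMIs. Urothelial-like cells were 0.209 times their D0 share at D7 (0.103 to 0.396; 13 cells against 44), and intercalated cell-like cells 1.30 times (0.874 to 1.95). Mesenchymal-like cells were 0 of 8526 at D0 at the floor, which allows a share of up to 0.0352%, and 0.372, 0.139 and 0.208% at D1, D4 and D7. Neutrophil-like cells were 2.53 times their D0 share at D7 at the floor (1.06 to 6.93), from 25 cells against 7, but 0.63 times over all kept cells (0.382 to 1.025; 29 cells against 46). At clustering resolution 1 no cluster was named endothelial, while at resolution 2 a cluster of 189 cells led by Iigp1, Cxcl10, Igtp and Fabp4 was. At resolution 1, 6.78, 7.95, 0.613 and 0.681% of kept cells had no class name.

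**Figure D1:**
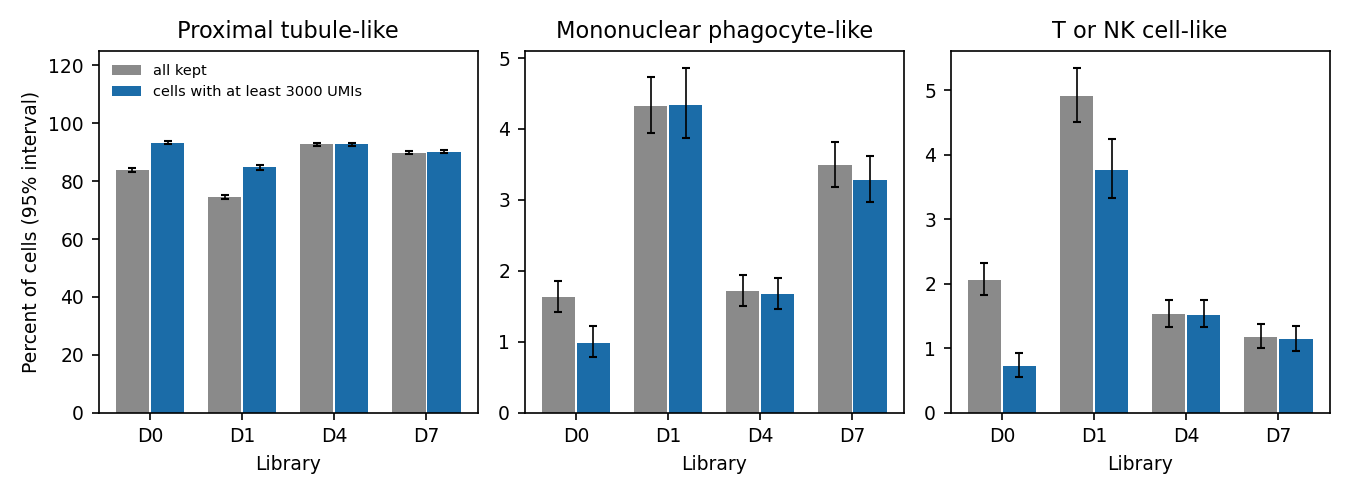
Shares of cell classes at D0, D1, D4 and D7 among all kept cells and among cells with at least 3000 UMIs. Proximal tubule-like cells were 93.3, 84.8, 92.7 and 90.1% of the latter, and mononuclear phagocyte-like cells 0.985, 4.34, 1.68 and 3.28%.

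RNA of the proximal tubule was measured in the other classes. It is called carried RNA, but free RNA and doublets with proximal tubule cells were not told apart, so the identity of the lymphoid cells at D4 and D7, their shares and their list values stay uncertain. In the T or NK cell-like, B cell-like, mononuclear phagocyte-like, thick ascending limb-like, distal tubule-like and intercalated cell-like classes this RNA stood higher at D4 and D7 than at D0. Over 11 proximal tubule markers, such as the solute carriers Slc34a1 and Slc22a6, the median level in T or NK cell-like cells was 16.3, 8.96, 72.2 and 63.1% of that in proximal tubule-like cells at D0, D1, D4 and D7. It was 13.9, 14.1, 76.5 and 58.0% in B cell-like cells, 71.4, 38.2, 78.5 and 68.4% in neutrophil-like cells and 11.6, 11.7, 45.5 and 19.5% in mononuclear phagocyte-like cells. Thick ascending limb-like cells held 4.23, 4.90, 21.1 and 17.3%, distal convoluted and connecting tubule-like cells 7.59, 5.95, 35.9 and 13.4%, and intercalated cell-like cells 21.1, 10.7, 44.5 and 25.5%. The reverse flow was small: over 6 thick ascending limb markers, such as Umod (uromodulin), proximal tubule-like cells held 0.078, 0.105, 0.137 and 0.199% of the thick ascending limb-like level. Single markers ranged from 0.027 to 0.152, 0.0 to 0.256, 0.067 to 0.271 and 0.091 to 0.271%. What this RNA gives in proximal tubule-like cells is computed below from the medians and is uncertain by this range. Over 9 phagocyte markers, such as the complement gene C1qa and the lysozyme gene Lyz2, proximal tubule-like cells held 0.031, 0.113, 0.114 and 0.160% of the phagocyte-like level.

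**Figure D2:**
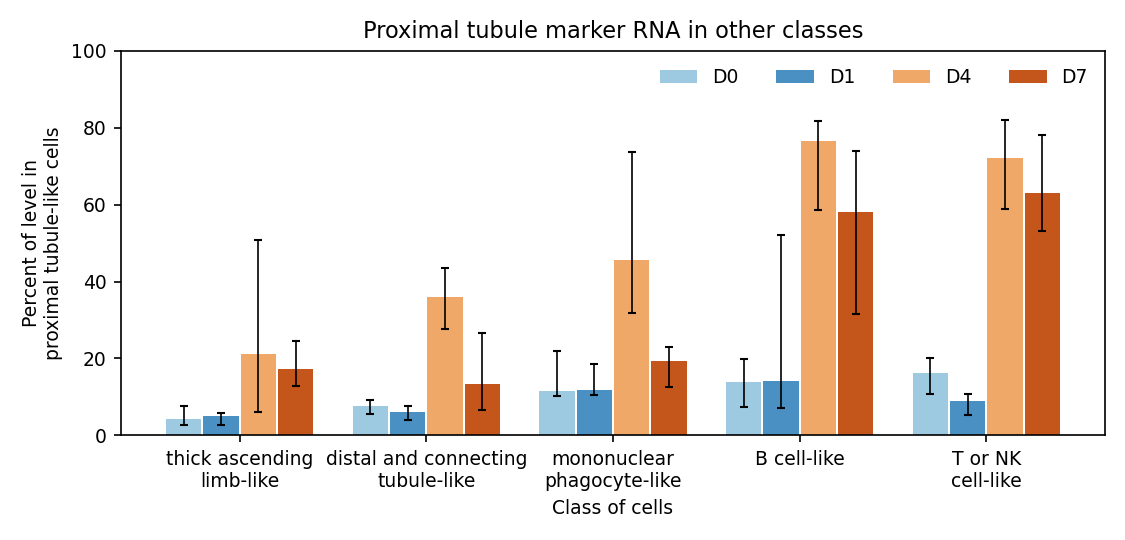
Median level of 11 proximal tubule markers in the other classes, as a percentage of the level in proximal tubule-like cells. In T or NK cell-like cells it was 16.3, 8.96, 72.2 and 63.1% at D0, D1, D4 and D7.

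In proximal tubule-like cells at D1, the actin-binding gene Tmsb4x was 2.43-fold higher than at D0 (2.29 to 2.58). Its level was highest in mononuclear phagocyte-like cells, and RNA of phagocyte-like, T or NK cell-like, B cell-like and neutrophil-like cells gives 13.8 of its 24.4 CPM at D0 and 35.3 of its 59.2 CPM at D1, with a ratio of 2.26 left. The glutathione transferase genes Gsta4 and Gsta2 were 2.05-fold (1.94 to 2.17) and 1.61-fold higher (1.59 to 1.63). The stress gene Gadd45g was 1.95-fold higher (1.91 to 2.00). Spp1 was at 470.2 CPM against 247 CPM, 1.90-fold higher (1.87 to 1.94). Cpn1 (a carboxypeptidase subunit) was 1.72-fold higher (1.67 to 1.77), Npl (a sialic acid lyase) 1.64-fold (1.56 to 1.72) and the transcription factor gene Cebpb 1.61-fold (1.55 to 1.67). The cluster that Npl leads held 9.14% of the class at D0 and 14.4% at D1. G6pc (glucose-6-phosphatase, the last step of glucose release) was lower at 0.479 times its D0 level (0.469 to 0.489), and Ttr (transthyretin) at 0.518 times (0.506 to 0.529). Also lower were Timp3 (a metalloproteinase inhibitor, 0.587; 0.580 to 0.594), AY036118 (0.583; 0.559 to 0.608), Arrdc3 (an arrestin-like adaptor, 0.584; 0.557 to 0.612) and Fosb (an immediate-early factor, 0.606; 0.578 to 0.636). Angptl4 (a lipase inhibitor) was at 0.610 times (0.583 to 0.638) and Hsd17b11 (a steroid dehydrogenase) at 0.614 times (0.591 to 0.638). Havcr1 had 328 UMIs against 7, or 5.50 CPM against 0.102 CPM, a ratio of 53.7 (25.8 to 135). Lcn2 (lipocalin 2, an iron-binding injury marker) had 63 UMIs against 3, a ratio of 24.1 (7.87 to 120), and thick ascending limb RNA alone gives 1.29 CPM of Lcn2 against the 1.06 CPM measured. Over 2243 genes the median log2 ratio at D1 was 0.16, and edgeR TMM factors move all D1 ratios by -0.11, so D1 list medians are read against these values. The median mitochondrial share of proximal tubule-like cells was 14.2, 8.57, 16.8 and 17.6% at D0, D1, D4 and D7, lowest at D1.

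At D4, Cryab (a small heat shock protein) was 6.64-fold higher than at D0 (6.25 to 7.06), Spp1 4.68-fold (4.61 to 4.76) and Id1 (an inhibitor of differentiation factors) 4.06-fold (3.85 to 4.27). The stress hormone gene Gdf15 was 3.56-fold higher (3.45 to 3.67) and the matrix signalling gene Cyr61 2.95-fold (2.87 to 3.04). Klf6 (a transcription factor of injury) was 2.94-fold higher (2.83 to 3.06), the tubulin gene Tubb5 2.91-fold (2.73 to 3.1) and the salt-regulating kinase gene Sgk1 2.85-fold (2.73 to 2.99). Acsm3 (a fatty acid activating enzyme) was lower at 0.420 times its D0 level (0.407 to 0.433) and the organic anion transporter gene Slco1a1 at 0.463 times (0.449 to 0.478). Lower as well were the lipid genes Fabp3 (0.550; 0.526 to 0.575), Lpl (0.559; 0.548 to 0.570) and Agps (0.562; 0.539 to 0.586), Gatm (creatine synthesis, 0.557; 0.550 to 0.563), Car3 (a carbonic anhydrase, 0.566; 0.549 to 0.582) and Hsd3b2 (a steroid dehydrogenase, 0.582; 0.560 to 0.606). Gatm, Car3 and Fabp3 are leading genes of the Npl-led cluster, with 9.14, 2.12 and 3.98% of the class at D0, D4 and D7. Sgk1 and Cyr61 are leading genes of the Txnip-led cluster, with 10.9, 24.2 and 18.5%. Slco1a1 and Lpl are leading genes of a cluster with 13.8, 14.2 and 12.0%. Class ratios mix such shifts between clusters with changes within cells, and these were not told apart. Havcr1 was at 19.6 CPM from 1359 UMIs, a ratio of 191 (92.5 to 476). Lcn2 was at 1.96 CPM from 136 UMIs, a ratio of 44.6 (15.0 to 219), of which thick ascending limb RNA gives 1.55 CPM.

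By D7, Wfdc2 (a secreted protease inhibitor of kidney scarring) was 18.9-fold higher than at D0 (16.4 to 21.7) and the stress factor gene Atf3 11.2-fold (10.2 to 12.3). The small heat shock genes Cryab and Hspb1 were 9.46-fold (8.92 to 10.04) and 8.72-fold higher (7.93 to 9.60), Spp1 8.83-fold at 2182 CPM, and the fibrinogen gene Fgg 8.47-fold (7.85 to 9.15). S100a6 (a calcium-binding protein) was 6.06-fold higher (5.56 to 6.62) and Id1 5.61-fold (5.33 to 5.89). Slco1a1 was at 0.395 times its D0 level, Acsm3 at 0.425 times (0.412 to 0.439), Car3 at 0.430 times (0.417 to 0.444) and G6pc at 0.443 times (0.434 to 0.452). Gatm was at 0.498 times (0.492 to 0.504), Hsd17b11 at 0.532 times (0.512 to 0.553), Spp2 (a secreted phosphoprotein) at 0.550 times (0.539 to 0.562) and Slc18a1 (a monoamine transporter) at 0.558 times (0.533 to 0.584). Havcr1 was at 27.1 CPM, and Lcn2 at 5.44 CPM from 383 UMIs against 3, a ratio of 124 (42.1 to 604), of which thick ascending limb RNA gives 2.86 CPM. Without the Havcr1-led cluster S100a6 was lower at 0.723 times (0.633 to 0.824). There Havcr1 was at a ratio of 111 (53.5 to 277), Wfdc2 13.2-fold (11.4 to 15.2), Cryab 8.37-fold (7.88 to 8.90), Fgg 7.15-fold (6.62 to 7.73) and Spp1 6.34-fold higher (6.23 to 6.44). Atf3 was then 8.06-fold (7.332 to 8.875), Hspb1 5.53-fold (4.97 to 6.17) and Id1 5.11-fold higher (4.85 to 5.38). Lcn2 was then at a ratio of 71.8 (24.2 to 351).

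Among the tubule injury genes in proximal tubule-like cells, Havcr1, Cryab, Spp1 and Fgg had ratios of 264, 9.46, 8.83 and 8.47 at D7. The list median was 0.78 in log2 at D1 (0.68 to 0.86), 1.44 at D4 (1.33 to 1.53) and 2.03 at D7 (1.92 to 2.13). At D7, 14 of 18 measured members were at least 1.5-fold higher by the ratio of CPM plus 1, 0 lower and 4 in between. All numbers of higher and lower list members use this ratio. Genes of low level can thus pass 1.5-fold in CPM and still lie in between, such as Timp2 at 0.781 CPM against 0.322 CPM. At D1 and at D4, 10 of 16 were higher, 0 lower and 6 in between. With thick ascending limb RNA taken off the medians were 0.56, 1.27 and 1.76, and that RNA gave 65.9% of the Clu (clusterin) level at D1 and 21.0% at D7. A pseudocount of 10 CPM gives medians of 0.21, 0.27 and 0.60, since many members lie below 10 CPM, and without the Havcr1-led cluster the D7 median was 1.35. Crystal-binding and stone-matrix genes had medians of 0.56, 0.61 and 0.82, with 5 of 8 higher, 0 lower and 3 in between at D7, such as Anxa2 (annexin A2) at 13.8-fold and Thbs1 (thrombospondin 1) at 23.4-fold, from 241 UMIs against 10.

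Proximal tubule transport genes stood lower at D1, with a median of -0.32 (-0.35 to -0.30) and 0 of 20 higher, 2 lower and 18 in between, the 2 being the neutral amino acid transporter genes Slc6a19 at 0.616 times and Slc7a8 at 0.658 times, named after their values were seen. Their median was -0.05 at D4 and -0.15 at D7 (-0.17 to -0.08), when the sulfate transporter gene Slc13a1 was 2.30-fold higher and Slc6a18 1.60-fold, so that 2 were higher, 1 lower and 17 in between. At D4 the median, inside the random range, was 0.04 with at most 25% mitochondrial UMIs and 0.003 with thinned cells. At D7 it was -0.04 and -0.07 under these settings. Glyoxylate and oxalate handling genes had medians of 0.07 at D1 (-0.04 with TMM factors), -0.08 at D4 and -0.11 at D7, inside the range of random lists. Here 1 of 11 was higher (Hao2, a hydroxyacid oxidase, 1.68-fold), 1 lower (Agxt2, an aminotransferase, 0.655 times) and 9 in between at D7. Gluconeogenesis and ammoniagenesis genes had medians of 0.10 at D1 (-0.004 with TMM factors), -0.24 at D4 and -0.34 at D7 (-0.36 to -0.32). At D7 G6pc was at 0.443 times, with Pck1 at 0.730 times and Slc38a3 (a glutamine transporter) 2.13-fold higher, so that 1 of 8 was higher, 1 lower and 6 in between. Fatty acid oxidation genes lay inside the random range at 0.23, -0.04 and 0.01 (-0.06 with TMM factors at D7), and all 19 were in between at D7, Acaa2 at 0.717 times. Nuclear oxidative phosphorylation genes also lay inside it at 0.11, -0.11 and -0.12, all 20 in between, with Sdhb at 0.813 times. Glycolysis and hypoxia response genes had medians of 0.26, -0.11 and 0.003 (-0.067 with TMM factors at D7), with 3 of 14 higher at D7, such as Pfkp at 3.02-fold, 0 lower and 11 in between.

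Among cytokine and NF-kB genes in proximal tubule-like cells, the neutrophil-drawing chemokine gene Cxcl1 was 24.2-fold higher at D7 (2219 UMIs against 89), and Csf1 (the macrophage growth factor) had 603 UMIs against 4, a ratio of 146. The list medians were 0.32, 0.54 and 1.08 (0.85 to 1.27 at D7), with 11 of 15 higher, 0 lower and 4 in between at D7. Immediate-early and dissociation response genes were at -0.20 at D1 (-0.24 to -0.16), 0.90 at D4 (0.88 to 0.93) and 0.91 at D7 (0.87 to 0.95). Of these, 12 of 16 were higher at D7, 0 lower and 4 in between, with Ier3 at 4.38-fold and Btg2 at 3.88-fold. Unfolded protein response genes were at -0.07, 0.41 and 0.37 (0.33 to 0.39 at D7), with Ddit3 (CHOP) at 2.06-fold and 3 of 13 higher, 0 lower and 10 in between at D7. The p53 target list was at 0.15, 0.39 and 0.47 (0.35 to 0.54 at D7), with Cdkn1a (p21) at 5.01-fold and Gdf15 at 4.84-fold, and 4 of 11 higher, 0 lower and 7 in between. NRF2 targets were at 0.27, 0.04 and 0.28, with Osgin1 at 1.66-fold and 1 of 11 higher, 0 lower and 10 in between at D7. Antioxidant enzymes stayed inside the random range at 0.12, -0.15 and -0.11, with Sod3 at 1.67-fold and 1 of 10 higher, 0 lower and 9 in between. Iron handling and ferroptosis genes did so too at 0.14, 0.002 (-0.025 with TMM factors) and 0.10, all 10 in between at D7, with the iron exporter gene Slc40a1 at 1.44-fold.

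Interferon response genes were at 0.24, 0.09 and 0.68 (0.56 to 0.79 at D7), with Ifit2 at 5.91-fold and Cxcl10 at 3.29-fold, and 6 of 12 higher, 0 lower and 6 in between. Matrix and fibrosis genes were at -0.06, 0.12 and 0.48, with Sparc at 2.88-fold and 3 of 8 higher, 0 lower and 5 in between at D7. Endothelial activation genes were at -0.07, 0.52 and 1.70 (1.56 to 1.82), with Edn1 (endothelin 1) at 25.6-fold and Plat (plasminogen activator) at 29.1-fold, and 4 of 6 higher, 1 lower and 1 in between at D7. The lower one was Esm1 with 2 UMIs against 48, named after its values were seen. With members of at least 1 UMI the D4 and D7 medians were -0.02 and -0.02, and without the Havcr1-led cluster 0.82 at D7. Antigen presentation genes were at 0.37, 1.10 and 1.82 (1.74 to 1.88), with Cd74 at 3.72-fold and H2-DMa at 5.35-fold, and 5 of 6 higher, 0 lower and 1 in between at D7. The phagocyte markers in proximal tubule-like cells were higher by a median of 3.83-fold at D7 (1.60 to 11.7 over 9 markers). By level, these markers stood at a median of 0.160% of the phagocyte-like level at D7, with a range from 0.093 to 1.08%. Of the list, H2-Ab1 stood at 1.93%, Cd74 at 1.10%, H2-DMa at 2.98% and Ciita at 3.17% of it. H2-Aa at 0.678% and H2-Eb1 at 0.918% lay within the range of the markers, but only because of Csf1r at 1.08%. The next highest marker was Cd68 at 0.232%. RNA of B cell-like cells was not taken into account in this comparison. Inflammatory phagocyte genes were at 0.67, 0.29 and 1.27, with Cxcl2 at 296 UMIs against 2, a ratio of 144 (39.5 to 1193), and 4 of 5 higher, 0 lower and 1 in between at D7. Il1b and Ccl3, which are among the higher ones, were at 3.98-fold and 2.68-fold. Ccl4, named after its values were seen, was at 1.73-fold (3.01 CPM against 1.74 CPM), but in between by CPM plus 1. Il1b, Ccl3 and Ccl4 stood at 0.192, 0.245 and 0.209% of the phagocyte-like level, near the 0.160% of the markers. Lipid-associated and repair phagocyte genes were at 0.40, 0.71 and 1.08, with Lgals3 (galectin 3) at 20.1-fold and Lpl at 0.621 times, and 3 of 6 higher, 1 lower and 2 in between at D7. The 3 measured monocyte genes were at 0.47 at D1 with 0 higher, 0 lower and 3 in between, and were too few at D4 and D7. Thick ascending limb transport genes were at -0.12, -0.16 and 0.08, with Fxyd2 at 0.78 times and 0 of 8 higher, 0 lower and 8 in between at D7. Their D7 median was -0.06 with Scrublet calls kept and -0.12 with thinned cells. Inside the random range also lay NRF2 targets, interferon response and inflammatory phagocyte genes at D4, matrix genes at D1 and D4, p53 targets, gluconeogenesis and endothelial activation genes at D1, glycolysis at D4 and D7, and thick ascending limb transport at D4 and D7. With a pseudocount of 10 CPM the D7 median was 0.13 for crystal-binding, 0.32 for cytokine, 0.21 for interferon response, 1.02 for antigen presentation and 1.07 for cell cycle genes. With members of at least 1 UMI it was 0.44 for interferon response, 0.55 for inflammatory phagocyte, 0.16 for lipid-associated and 0.21 for matrix genes. With thinned cells it was 1.99 for crystal-binding genes, and without the Havcr1-led cluster 0.72 for lipid-associated genes.

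**Figure D3:**
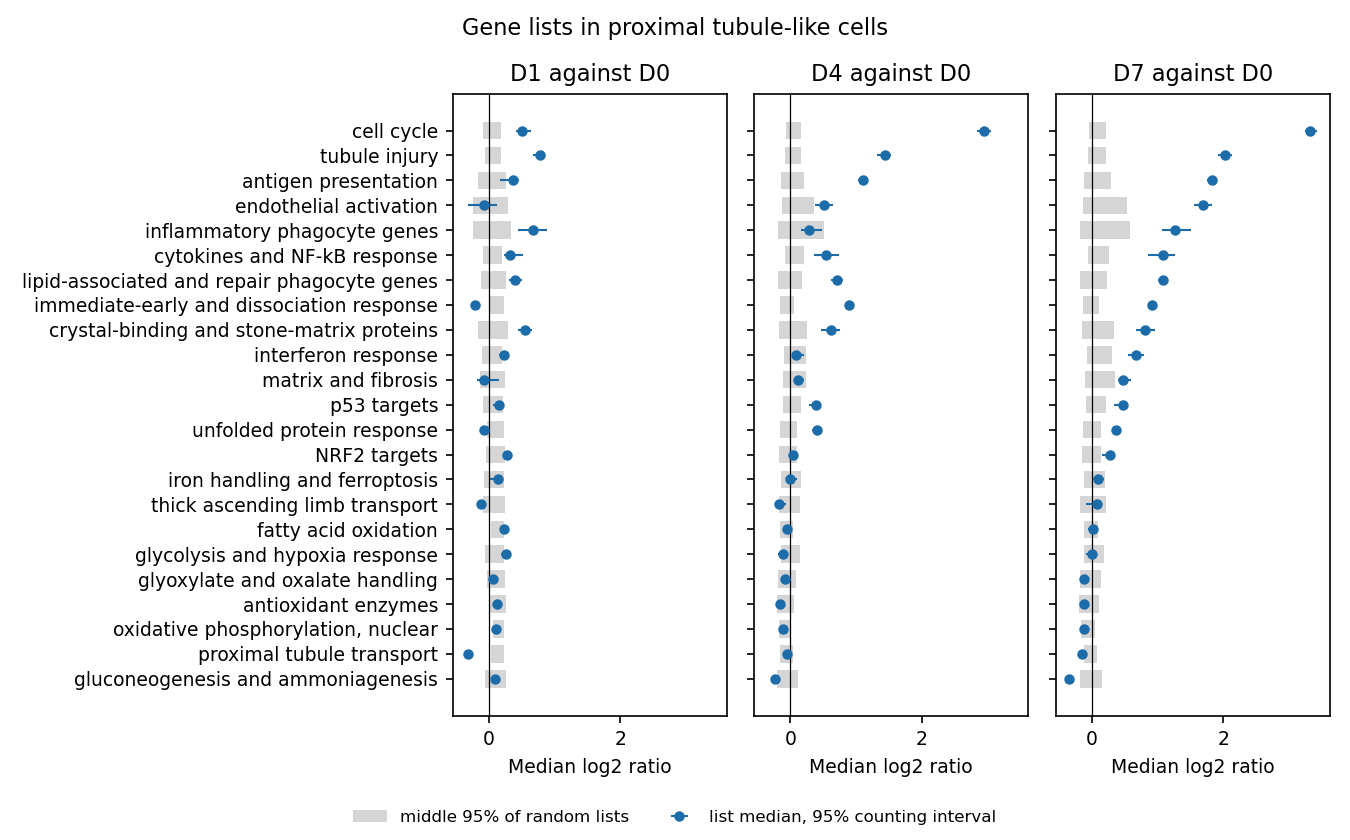
Median log2 ratios of the gene lists in proximal tubule-like cells at D1, D4 and D7 against D0, with the range of random lists. The tubule injury list was at 0.78, 1.44 and 2.03, and 3 list directions turn with TMM factors at D7 or D4: fatty acid oxidation from 0.01 to -0.06, glycolysis from 0.003 to -0.067 and iron handling from 0.002 to -0.025, as do 2 at D1, glyoxylate from 0.07 to -0.04 and gluconeogenesis from 0.10 to -0.004.

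Cell cycle genes in proximal tubule-like cells were higher at D4 and D7: Mki67 (a protein of dividing cells) had 30, 101, 1423 and 1915 UMIs at D0, D1, D4 and D7, and Top2a 23, 86, 1277 and 1871. The list median was 0.50 at D1, 2.95 at D4 (2.84 to 3.05) and 3.32 at D7 (3.24 to 3.43), with 15 of 16 higher, 0 lower and 1 in between at D7. Without the Havcr1-led and the cell cycle clusters the medians were 0.22, 0.81 and 0.83. These clusters were named proximal tubule at scores of 0.264 and 0.310, with 12 markers detected in each. Other clusters of the class scored 0.325 to 0.629. As lymphoid classes also held much proximal tubule RNA at D4 and D7, the identity of these clusters is less certain. After thinning each cell to 1000 UMIs, which left out 648 and 590 cells at D0 and D1, Mki67 was found in 0.0397% of proximal tubule-like cells at D0 (0.0108 to 0.102), 0.155% at D1 (0.0772 to 0.276), 1.30% at D4 (1.11 to 1.51) and 1.28% at D7 (1.08 to 1.5). Unthinned shares were 0.177, 0.454, 3.15 and 3.51%. Distal convoluted and connecting tubule-like cells had Mki67 in 0 of 300 cells at D0 (up to 1.00%), 0.559% at D4 (0.0141 to 3.07) and 0.803% at D7 (0.0974 to 2.87). Their median depths were 4956, 4806 and 4811 UMIs, and it was not examined whether some of them divide. The class share lies inside these wide intervals. In the cluster led by cell cycle genes, 21.1% of cells had Mki67 at D4 (17.8 to 24.7) and 30.4% at D7 (26.2 to 34.9). Both are above the intervals of the distal tubule-like cells. Cell cycle genes of the list were left out of clustering, but Cdc20, Hmmr, Cdca3 and Prc1, which also lead this cluster, were not among them. Mki67 is itself one of its leading genes, so this gap is no separate support. In the proximal tubule-like clusters led neither by Havcr1 nor by cell cycle genes, 0.0898% of cells had Mki67 at D4 (0.0448 to 0.161) and 0.125% at D7 (0.0664 to 0.213).

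Havcr1 was found in 0 of 10077 thinned proximal tubule-like cells at D0, which allows a share of up to 0.0298%, in 0.281% at D1 (0.172 to 0.434), 1.15% at D4 (0.970 to 1.34) and 1.41% at D7 (1.20 to 1.65), with unthinned shares of 0.0653, 1.28, 3.33 and 4.99%. Mononuclear phagocyte-like cells had it in 0 of 240 at D4, which allows up to 1.25%, and in 0.224% at D7 (0.0057 to 1.24), at median depths of 4126.5 and 3970.5 UMIs. Distal convoluted and connecting tubule-like cells had it in 1.12% at D4 (0.136 to 3.98) and 0 of 249 at D7 (up to 1.20%), at median depths of 4806 and 4811 UMIs. The intervals of the class share overlap those of both backgrounds. In the Havcr1-led cluster, 25.7% of cells had it at D4 (19.6 to 32.5) and 14.8% at D7 (12.1 to 17.9), above both backgrounds. This cluster was built without Havcr1 but was picked because Havcr1 is its leading gene, so this gap is no separate support. T or NK cell-like cells had it in 1.40 and 1.99%, from 3 cells each, but held so much proximal tubule RNA that they give no background. Outside the Havcr1-led and cell cycle clusters it was 0.784% at D4 (0.635 to 0.956) and 0.816% at D7 (0.652 to 1.01). Spp1 was found in 14.9, 19.8, 38.5 and 49.1% of thinned proximal tubule-like cells (unthinned 31.8, 44.6, 67.6 and 79.6%). It was found in 0.810, 6.30, 28.8 and 40.4% of T or NK cell-like cells, which give no background here either. Mononuclear phagocyte-like cells had it in 3.54, 7.92, 22.9 and 19.7%, and distal convoluted and connecting tubule-like cells in 54.3, 79.1, 83.8 and 94.8%. Lcn2 was found in 0.0198, 0.211, 0.169 and 0.296% of thinned proximal tubule-like cells (unthinned 0.028, 0.610, 0.615 and 1.47%). Vcam1 was found in 0.0099, 0, 0.0923 and 0.288% (0 of 7119 at D1 allows up to 0.0421%; unthinned 0.0466, 0.0389, 0.438 and 1.19%). Krt20 (an injury keratin) was found in 0.0099, 0.014, 0.0154 and 0.0436% (unthinned 0.0839, 0.182, 0.231 and 0.445%). In the Havcr1-led cluster, built without these 3 genes, Vcam1 was found in 3.83% of cells at D7 (2.44 to 5.69), above the 0.897% in mononuclear phagocyte-like cells (0.245 to 2.28) and the 0 of 249 distal tubule-like cells (up to 1.20%). Krt20 was found there in 1.33% (0.576 to 2.61), against 0 of 446 (up to 0.673%) and 0 of 249, and Lcn2 in 2.33% (1.28 to 3.88), against 0.673% (0.139 to 1.95) and 12.4% (8.62 to 17.2), so these 2 are not separated from the backgrounds.

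**Figure D4:**
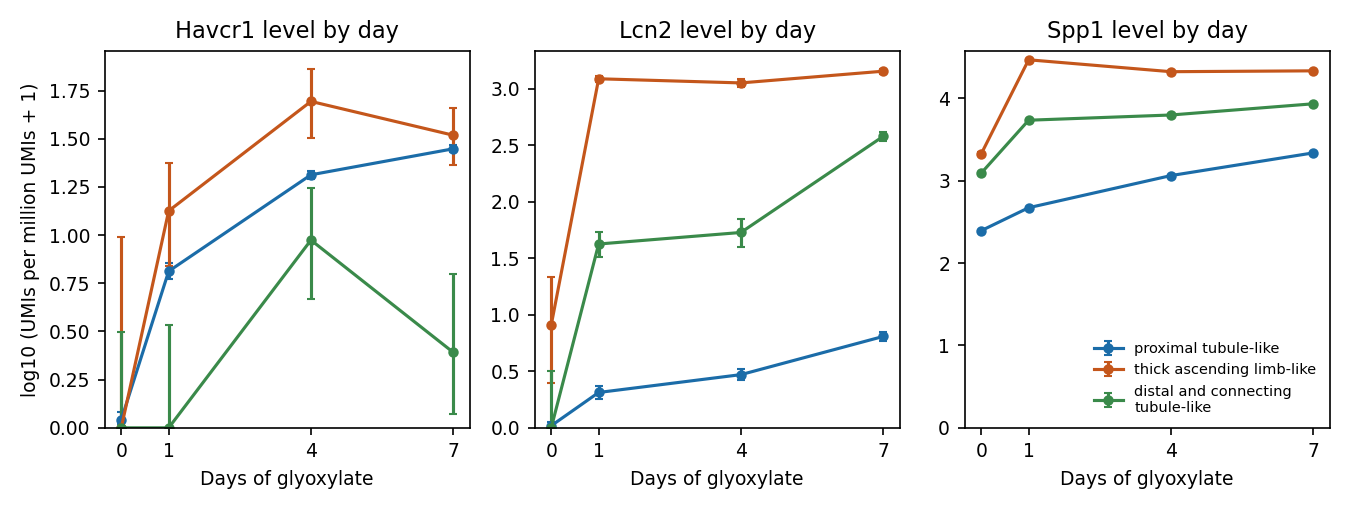
Levels of Havcr1, Lcn2 and Spp1 by cell class and day. Lcn2 was at 7.14, 1230 and 1435 CPM in thick ascending limb-like cells at D0, D1 and D7, and Havcr1 at 0.102, 5.50 and 27.1 CPM in proximal tubule-like cells. In thick ascending limb-like cells Havcr1 was at 0.0, 12.4 and 32.0 CPM on these days, from 0, 10 and 33 UMIs.

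In mononuclear phagocyte-like cells at D7, the genes of alternative activation Retnla, Arg1 and Ccl17 were higher than at D0. Retnla had 486 UMIs against 0, at least 46.0-fold. Arg1 had 204 against 0, at least 19.3-fold, and Ccl17 (a T cell chemokine) 157 against 0, at least 14.9-fold. Retnla was at 634 and 1443 CPM at D1 and D4 and 228 CPM at D7. The interferon-induced chemokine gene Cxcl9 was lower at 0.061 times its D0 level (0.044 to 0.083), Pglyrp1 (a peptidoglycan receptor) at 0.175 times (0.119 to 0.254) and Lilra5 (a leukocyte receptor) at 0.189 times (0.140 to 0.254). Spp1 was at 948 CPM against 46.1 CPM, of which carried proximal tubule RNA gives 424 CPM, Havcr1 had 3 UMIs against 0 and Lcn2 14 against 0, at least 1.33-fold. The Lyz2-led cluster held 83.2% of these cells at D7 (371 cells) and 44.7% at D0 (93 cells), and the C1qa-led cluster the other 75 and 115 cells, so class ratios mix the 2.

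Lipid-associated and repair phagocyte genes in the class were at 1.03 (0.62 to 1.35), with Fabp5 at 6.74-fold and Trem2 at 3.02-fold, and 6 of 10 higher, 1 lower and 3 in between. Their median was 2.13 in the Lyz2-led cluster (7 of 10 higher), but -0.33 in the C1qa-led one (1 of 6 higher, 2 lower). Antigen presentation genes were at -1.23 (-1.26 to -1.20), with H2-Eb1 at 0.374 times and Cd74 at 0.419 times, 0 of 6 higher, 4 lower and 2 in between. At the 3000 UMI floor this was -0.60, in the Lyz2-led cluster 0.20 and in the C1qa-led cluster -1.29. The interferon response list was at -0.94 (-1.20 to -0.64), with Cxcl10 at 0.214 times and Irf7 at 0.341 times, 0 of 12 higher, 8 lower and 4 in between, and at -1.30 in the Lyz2-led and -0.92 in the C1qa-led cluster. Cytokine and NF-kB genes were at 0.73 (0.34 to 1.04), with Ccl2 (a monocyte chemokine) 9.86-fold higher (6.87 to 14.7) and Cxcl2 4.84-fold (3.90 to 6.06), 7 of 14 higher, 3 lower and 4 in between. Inflammatory phagocyte genes were at -0.10, inside the random range, with Ccl3 at 0.429 times and 2 of 8 higher, 2 lower and 4 in between, but at 0.98 in the Lyz2-led cluster and 0.40 at the floor. Immediate-early genes were at -0.54 (-0.62 to -0.45), with Jun at 0.427 times, 1 of 16 higher, 8 lower and 7 in between, and at -0.18 in the Lyz2-led cluster. Monocyte genes were at 0.08, with Chil3 at 3.43-fold and Ly6c2 at 0.373 times, 3 of 9 higher, 2 lower and 4 in between, but at -0.59 at the floor. The 3 measured cell cycle genes were at 2.74, all higher, such as Birc5 at 57 UMIs against 1, a ratio of 16.2 (2.79 to 651). The thinned share of these cells with a UMI of Mki67 was 1.01% at D0 (0.123 to 3.6), 1.32% at D1, 1.67% at D4 and 1.12% at D7 (0.365 to 2.60). The cell cycle gene Ube2c was at 27.6 CPM in these cells at D7 and at 41.1 CPM in proximal tubule-like cells.

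Carried proximal tubule RNA in these cells was 11.6% of the proximal tubule level at D0 and 19.5% at D7, and the lists below were not recomputed without it. Transport genes were at 0.60 (9 of 14 higher, 0 lower, 5 in between), with Slc13a1 at 7.04-fold, glyoxylate genes at 0.84 (5 of 8 higher, 0 lower, 3 in between), with Hao2 at 3.67-fold, and fatty acid oxidation genes at 0.51 (6 of 17 higher, 0 lower, 11 in between). Oxidative phosphorylation genes were at 0.33 (0 of 20 higher, 0 lower), antioxidant enzymes at 0.36 (2 of 10 higher, 0 lower, 8 in between) and NRF2 targets at 0.53 (2 of 9 higher, 0 lower, 7 in between), with Hmox1 (heme oxygenase) at 2.01-fold. Injury genes were at 0.74 (3 of 5 higher, 0 lower, 2 in between) and crystal-binding genes at 0.97 (4 of 7 higher, 0 lower, 3 in between), with Fn1 (fibronectin) at 3.4-fold. Inside the random range lay gluconeogenesis at 0.02 (2 of 7 higher, 1 lower), glycolysis at 0.41 (2 of 8 higher, 0 lower), iron handling at 0.36 (2 of 7 higher, 0 lower) and the unfolded protein response at -0.10 (0 of 11 higher, 1 lower). So did p53 targets at 0.39 (2 of 6 higher, 1 lower), matrix genes at -0.25 (0 of 3 higher, 1 lower) and thick ascending limb transport at 0.27 (1 of 5 higher, 1 lower). Of the endothelial activation genes only Icam1 was measured, at 0.957 times (0.566 to 1.69).

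In distal convoluted and connecting tubule-like cells at D7 (249 cells against 314), Lcn2 had 518 UMIs against 0, at least 217-fold higher, at 380 CPM. Atf3 was 14.0-fold higher (9.10 to 22.4) and Spp1 6.96-fold (6.64 to 7.29) at 8617 CPM, of which carried proximal tubule RNA gives 291 CPM. Col5a2 (a collagen) was lower at 0.36 times (0.248 to 0.512), Wfdc15b (a protease inhibitor) at 0.424 times (0.396 to 0.454) and Atp4a (a proton pump) at 0.438 times (0.337 to 0.564). Havcr1 had 2 UMIs against 0, and Umod, a thick ascending limb gene, was at 3522 CPM at D0 and 3831 CPM at D7 against 11642 and 9676 CPM in thick ascending limb-like cells. Of the 6 thick ascending limb markers, Umod, Egf and Ppp1r1a were at 39.6, 66.7 and 88.8% of their level in that class at D7, but Slc12a1, Cldn16 and Tmem207 at 0.979, 1.56 and 0%, from 21, 3 and 0 UMIs. The Umod share would give 568 CPM of Lcn2 and 8577 CPM of Spp1 at D7, but at D1 587 CPM of Lcn2 against 41.4 CPM measured and 14083 CPM of Spp1 against 5443 CPM measured. The Slc12a1 share gives 14.1 CPM of Lcn2 and 212 CPM of Spp1 at D7. The median mitochondrial share of distal tubule-like cells fell from 33.5% at D0 to 17.9% at D7, and the median log2 ratio over 1987 genes was 0.21. Injury genes were at 1.24 (1.15 to 1.52), with Sox9 at 4.44-fold and 8 of 10 higher, 0 lower and 2 in between, and immediate-early genes at 2.00 (1.86 to 2.08), with Jun at 4.79-fold and 15 of 16 higher, 0 lower and 1 in between. Oxidative phosphorylation genes were at -0.18 (-0.25 to -0.15), with Cox8a at 0.762 times and all 20 in between. Among cells with at most 25% mitochondrial UMIs, a limit added after the data were seen (159 cells against 85, at median shares of 11.1 and 16.1%), these 3 medians were 1.15 (0.850 to 1.46), 1.35 (1.24 to 1.51) and -0.25 (-0.36 to -0.22). Transport genes of the proximal tubule were at 0.54 (4 of 8 higher, 0 lower) and glyoxylate genes at 1.10 (5 of 7 higher, 0 lower), with proximal tubule RNA at 7.59% at D0 and 13.4% at D7. Inside the random range lay crystal-binding genes at 0.19 (1 of 3 higher), fatty acid oxidation at 0.12 (3 of 18 higher), gluconeogenesis at 0.29 (2 of 5 higher), glycolysis at 0.08 (1 of 12 higher, 1 lower) and NRF2 targets at 0.33 (0 of 8 higher). The same held for antioxidant enzymes at 0.13 (2 of 9 higher), iron handling at 0.32 (2 of 8 higher, 2 lower), the unfolded protein response at 0.01 (2 of 11 higher), p53 targets at 0.50 (3 of 6 higher), thick ascending limb transport at -0.14 (1 of 8 higher, 1 lower) and lipid-associated genes at 0.33 (3 of 6 higher, 1 lower).

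In T or NK cell-like cells at D7 (151 cells against 264), the lymphocyte genes Dapl1, Cxcr6 (a homing receptor) and Ifng (interferon gamma) were lower at 0.132 (0.077 to 0.214), 0.206 (0.145 to 0.289) and 0.211 times their D0 level (0.144 to 0.302). These cells held 63.1% of the proximal tubule marker level at D7 against 16.3% at D0. If this is the proximal tubule share of their UMIs, their own genes fall to 0.441 times, or -1.18 in log2, by dilution alone. The 3 highest genes were Hspa1a with 109 UMIs against 1, a ratio of 96.8 (17.0 to 3859), Cyr61 with 120 against 3, a ratio of 35.5 (11.9 to 175), and Gdf15 with 138 against 4, 30.6-fold higher (11.7 to 114). All 3 were at or below the level that carried RNA gives, for Gdf15 178 CPM against 217 CPM, as was Spp1 at 1265 CPM against 1377 CPM. Havcr1 had 8 UMIs against 0, at least 2.37-fold, and Lcn2 1 against 0. Interferon response genes were at -1.36 (-1.83 to -0.88), with 0 of 3 higher, 3 lower and 0 in between, which is not beyond the dilution. Monocyte genes were at -1.0, with Ly6c2 at 0.248 times and 0 of 4 higher, 4 lower and 0 in between. Lists of proximal tubule genes were higher: transport 2.14 (15 of 15 higher), glyoxylate 2.15 (7 of 7), gluconeogenesis 1.44 (6 of 7), antioxidant enzymes 1.38 (9 of 10), fatty acid oxidation 1.20 (10 of 12) and oxidative phosphorylation 0.88 (18 of 20). So were injury genes at 2.71 (2 of 3 higher), iron handling at 1.56 (2 of 3), thick ascending limb transport at 1.38 (4 of 5, 1 lower) and lipid-associated genes at 1.29 (4 of 5). No other member of these 10 lists was lower. Inside the random range lay immediate-early genes at 0.28 (4 of 14 higher, 4 lower), cell cycle genes at -0.59 (0 of 6 higher, 4 lower), cytokine genes at -0.77 (0 of 3 higher, 2 lower), glycolysis at 0.56 (4 of 8 higher, 2 lower) and NRF2 targets at 0.98 (5 of 7 higher). Also inside it were crystal-binding genes at 0.13 (2 of 4 higher), the unfolded protein response at 0.15 (2 of 9 higher) and p53 targets at 0.004 (1 of 4 higher).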

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

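Of the tests below, the one on recovery of tubule cells and both on Mki67 were chosen only after the result was seen, as was the repetition over 20 thinning draws, which followed single draws that differed. The floor of 3000 UMIs and leaving out the cluster led by Havcr1 were added after the data were seen, with limits set before these results were seen.

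The tubule injury genes, led by Havcr1, Cryab, Spp1 and Fgg, had a higher median log2 ratio of 2.03 in proximal tubule-like cells at D7. Among cells with at least 3000 UMIs the median was 2.10 (1.98 to 2.22), which argues against the different cell-calling floors. Among cells without a UMI of Fos, Jun, Egr1 or Atf3 it was 1.70 (1.49 to 1.87), so the rise was not confined to cells with these transcripts. Such cells were 58.2% of the class at D0 and 34.0% at D7, and lack of a UMI does not mark an unstressed cell. This subset therefore cannot decide on a difference in dissociation between the libraries. Without the cluster led by Havcr1 the list median was 1.35 (1.21 to 1.43), so the rise was not confined to the cells of that cluster. Leaving the cluster out removes neither RNA carried from its cells nor injured cells placed in other clusters. It therefore cannot decide whether a small group of strongly injured cells gave the pattern. An effect of the days of glyoxylate may explain the pattern, but it stays untested, since library and day cannot be told apart with 1 library per time point.

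Mononuclear phagocyte-like cells had a 2.14 times higher share at D7 than at D0, but 1.26 against 0.931% at resolution 2 and 1.40 against 1.04% with at most 25% mitochondrial UMIs, when the Lyz2-led cluster had no class name, with dendritic cell as its best class (scores of 0.429 and 0.463). At one floor of 3000 UMIs the ratio was 3.33 (2.63 to 4.27). That floor kept 84 of 208 phagocyte-like cells at D0 and 395 of 446 at D7. Over all kept cells their median depths were 2578.5 and 3970.5 UMIs. Since the floor removes these cells unevenly, it cannot decide whether cell calling plays a part in the ratio. A lower recovery of tubule cells would raise other classes alike, and the T or NK cell-like share was 1.57 times higher (1.15 to 2.15), below the phagocyte ratio. The B cell-like ratio of 2.83 (1.52 to 5.67) overlaps it, so recovery may still play a part. Over all kept cells both lymphoid ratios point the other way, 0.572 (0.465 to 0.701) for T or NK cell-like and 0.341 (0.247 to 0.465) for B cell-like cells, where the cell-calling floors differ. The floor of 3000 UMIs leaves 62 of 264 T or NK cell-like and 13 of 164 B cell-like cells at D0. Influx of phagocytes with glyoxylate stays open and untested.

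Proximal tubule-like cells with a UMI of Mki67 were more frequent at D4 and D7 than at D0. Among cells with at least 3000 UMIs the D4 share was at least 14.3 times that at D0 in each of 20 draws, where the draw with the lowest limit had an interval from 6.42 to 39.8, which argues against the cell-calling floors. Cells with a Mki67 UMI held a median of 2.0 other cell cycle genes in the least favourable draw and 3.0 in the most favourable, against 0 in cells without, which argues against free RNA of cycling cells of other types as the whole cause. It cannot decide on doublets with such cells, which would also hold several of these genes. The thinned share was 32.7 times higher at D4 than at D0 in proximal tubule-like cells, from 4 cells at D0, and 4.02 times in T or NK cell-like cells, whose own share of 6.51% at D4 (3.61 to 10.7) was above the 1.30% in proximal tubule-like cells. Tubule cells that enter the cell cycle after days of glyoxylate are a possible explanation, untested with 1 library per time point.

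Several list medians had opposite directions in different classes or days, and none of these differences was tested. Proximal tubule transport genes at D7 were at -0.15 in proximal tubule-like cells, against 0.54 in distal convoluted and connecting tubule-like cells (a difference of -0.68). They were at 0.60 in mononuclear phagocyte-like cells (-0.75) and at 2.14 in T or NK cell-like cells (-2.29). Gluconeogenesis genes were at -0.34 in proximal tubule-like cells and 1.44 in T or NK cell-like cells (-1.78). The other classes held more proximal tubule RNA at D7 than at D0, in T or NK cell-like cells 63.1% against 16.3% of the proximal tubule level. Unfolded protein response genes in proximal tubule-like cells were at 0.37 at D7 and -0.07 at D1 (0.44). Immediate-early genes were at 0.91 in proximal tubule-like cells at D7, against -0.20 at D1 (1.11) and -0.54 in mononuclear phagocyte-like cells at D7 (1.45). At D4 the unfolded protein response list was at 0.41 and the immediate-early list at 0.90, so both split by the pairs of libraries with different cell calling. Of the proximal tubule-like cells 58.2 and 58.3% had no UMI of Fos, Jun, Egr1 or Atf3 at D0 and D1, but 31.9 and 34.0% at D4 and D7. Interferon response genes were at 0.68 in proximal tubule-like cells, against -0.94 in mononuclear phagocyte-like cells (1.62) and -1.36 in T or NK cell-like cells (2.03). In the latter, from 3 genes (-1.83 to -0.88), dilution by proximal tubule RNA alone would give -1.18, and in the phagocyte-like cells -0.13. Antigen presentation genes were at 1.82 in proximal tubule-like cells and -1.23 in mononuclear phagocyte-like cells (3.06). The latter was -0.60 at the 3000 UMI floor and 0.20 in the Lyz2-led cluster, which held 83.2% of these cells at D7 against 44.7% at D0. In the C1qa-led cluster it was about as low as in the whole class.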

How the results depend on the processing

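The alternatives chosen only after the data were seen were the common floor of 3000 UMIs, the automatic Scrublet threshold, leaving out clusters, shares without thinning and the limit of 25% mitochondrial UMIs within the named distal tubule-like and thick ascending limb-like cells, whose values stand beside the main ones. No paired analysis was possible because each group has 1 library. The cause of the changes below was not tested, except where it follows from how the alternative is built.

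With at most 25% mitochondrial UMIs the proximal tubule-like share was 86.2% at D0 and 89.0% at D7. The mononuclear phagocyte-like share was 1.04, 1.58, 0.776 and 1.40% at D0, D1, D4 and D7, since the Lyz2-led cluster then had no class name and scored best as dendritic cell. The injury list median at D7 was 2.13, and the transport list was at 0.042 at D4 and -0.042 at D7. With at least 1000 UMIs the proximal tubule-like share was 85.2% at D0 and 76.9% at D1. At resolution 2 the mononuclear phagocyte-like share was 0.931, 1.53, 0.741 and 1.26%, for the same reason of naming.

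With Scrublet calls kept the proximal tubule-like share was 82.6, 73.4, 91.8 and 88.0%, and the mononuclear phagocyte-like share 1.96% at D0, 1.96% at D4 and 4.05% at D7. The injury median at D4 was then 1.28. With the automatic threshold the proximal tubule-like share was 82.2, 73.2 and 93.2% at D0, D1 and D4, and the mononuclear phagocyte-like share 1.96% at D0. At the common floor of 3000 UMIs the proximal tubule-like share was 93.3% at D0 and 84.8% at D1, the mononuclear phagocyte-like share 0.985% at D0, and the Lcn2 share 0.0% at D0.

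A pseudocount of 10 CPM gave injury medians of 0.21, 0.27 and 0.60 at D1, D4 and D7, since it shrinks genes under 10 CPM, and a transport median of -0.30 at D1. Thinned cells gave injury medians of 1.88 at D4 and 2.29 at D7, and transport medians of -0.37, 0.003 and -0.071. TMM factors gave transport medians of -0.43, -0.081 and -0.21. Without the Havcr1-led cluster the injury medians were 1.06 at D4 and 1.35 at D7, and without the cell cycle cluster as well 1.04 and 1.33, with a transport median of -0.007 at D4.

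Among named genes and lists outside the random range in proximal tubule-like cells, the direction reversed for S100a6 at D7, to -0.41 without the Havcr1-led cluster and -0.44 without both clusters, and for endothelial activation genes with members of at least 1 UMI, to -0.022 at D4 and -0.021 at D7. Lists inside the random range also turned under some settings, among them transport at D4, fatty acid oxidation, glycolysis and thick ascending limb transport at D7, iron handling at D1 and D4, NRF2 targets at D4, and glyoxylate, gluconeogenesis, matrix and endothelial activation genes at D1.

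Without thinning, which by construction lets deeper cells show more genes, the Havcr1 shares were 0.065, 1.28, 3.33 and 4.99%. Lcn2 shares were 0.61, 0.615 and 1.47% at D1, D4 and D7, and Spp1 shares 31.8, 44.6, 67.6 and 79.6%. Vcam1 shares were 0.438 and 1.19% at D4 and D7, Krt20 shares 0.084, 0.182, 0.231 and 0.445%, and Mki67 shares 0.177, 0.454, 3.15 and 3.51%.

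Of the secondary values, 83 moved beyond counting error with the 10 CPM pseudocount, 75 with thinned cells, 65 with TMM factors, 58 without both clusters, 52 with the mitochondrial limit and 43 without the Havcr1-led cluster. Another 31 moved with the automatic threshold, 26 with Scrublet calls kept, 21 at the common floor, 18 at resolution 2, 15 with 1 UMI and 10 with at least 1000 UMIs.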

Other observations

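All values in this part were chosen after they were seen, since thick ascending limb-like cells had 91 cells at D0, below the minimum of 100 fixed for a class.

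In thick ascending limb-like cells, a salt-reabsorbing segment, Lcn2 was at 7.14, 1230, 1130 and 1435 CPM at D0, D1, D4 and D7. From 3 UMIs at D0 its ratio was 172 at D1 (58.8 to 837) and 201 at D7 (68.7 to 976). Havcr1 was at 0.0, 12.4, 48.4 and 32.0 CPM in these cells at D0, D1, D4 and D7, from 0, 10, 24 and 33 UMIs. In proximal tubule-like cells it was at 0.102, 5.50, 19.6 and 27.1 CPM, so its rise was not particular to them. Clu was 54.1-fold higher at D1 (37.3 to 81.5) and 20.8-fold at D7 (14.3 to 31.4), and Spp1 13.9-fold (13 to 14.9) and 10.2-fold (9.55 to 10.9). The junction gene Cldn10 was lower at 0.327 times at D1 (0.278 to 0.383), and the potassium channel gene Kcnj1 at 0.698 times (0.557 to 0.874) and at D7 0.603 times (0.484 to 0.752). Injury genes had list medians of 2.19, 1.82 and 1.86 at D1, D4 and D7, with 7 of 9, 6 of 8 and 8 of 10 higher and 0 lower. Thick ascending limb transport genes were at -0.39, -0.91 and -0.51, with 2, 5 and 4 of 9 lower and 0 higher. Oxidative phosphorylation genes were at -0.38, -0.29 and -0.29, and immediate-early genes at 0.24, 0.99 and 1.22. The median mitochondrial share of these cells was 25.7% at D0 and 13.3, 14.0 and 11.3% at D1, D4 and D7. Among cells with at most 25% mitochondrial UMIs (44 cells at D0, with a median share of 17.1%) the list medians at D7 were 1.97 for injury, -0.39 for thick ascending limb transport, -0.43 for oxidative phosphorylation and 0.74 for immediate-early genes. Those at D1 were 2.08, -0.12, -0.40 and 0.03, and those at D4 1.88, -0.51, -0.37 and 0.60. Proximal tubule RNA in these cells was 4.23, 4.90, 21.1 and 17.3% of the proximal tubule level. If this is its share of their UMIs, dilution alone moves their own genes by -0.01, -0.28 and -0.21 in log2 at D1, D4 and D7.

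In proximal tubule-like cells, thick ascending limb RNA at the median marker share gave 122, 79.2 and 52.6% of the Lcn2 level at D1, D4 and D7. It gave 6.58, 2.51 and 1.98% of the Spp1 level and 0.24, 0.34 and 0.24% of the Havcr1 level. The 6 marker shares ranged from 0.0 to 0.256% at D1 and from 0.091 to 0.271% at D7, around medians of 0.105 and 0.199%. Of these markers, Umod, Egf and Ppp1r1a were also high in distal tubule-like cells, at 39.6, 66.7 and 88.8% of the thick ascending limb-like level at D7. The Lcn2 values are therefore rough and may be overstated.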
